A study of Xenopus laevis x Xenopus muelleri with 8 samples.

How the data were processed

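RNA from 8 ovary samples of hybrid frogs had been hybridised to Affymetrix Xenopus laevis arrays, with biotin-labelled target made from total RNA per the labels' protocols. Samples were grouped by their titles into 4 normal and 4 sex-reversed ovaries. The titles call them biological replicates, and nothing further says how the animals were related, so p-values measure the spread between these samples. The deposited values are log2 expression per probe set, made by RMA per the submitters' processing notes, which give no version. RMA corrects background, quantile normalizes the arrays and summarises the probes of each probe set. The log base is not stated in the sources used here and was read as 2 from RMA and the range of the values. Probe-set filters are not given in the sources used here, and the table held 0 control probe sets. Scanner files were not used here, so detection above background was not tested. Because RMA brings the arrays to a common distribution, a change shared by most transcripts would not show. The probes were designed on X. laevis, so a sequence difference in the X. muelleri allele or between laevis animals can lower a probe set's value without a change in transcript level.

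Gene symbols came from the platform annotation, which can be old. Of 11485 probe sets 6798 had 1 gene symbol, 110 had several and 4577 had none listed, and only the first kind was named. Homeologs were treated as separate genes. For gene lists, each of 5790 genes was represented by its probe set with the highest mean over all 8 arrays.

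Analyses used R 4.3.3 and limma 3.58.1, and figures used Python 3.11.15 with matplotlib 3.10.9. Each probe set was fitted on all 8 arrays with lmFit and eBayes, two-sided, with no covariate and no filter, and Benjamini-Hochberg adjusted p values under 0.05 counted as passing. Whole profiles were compared by a pseudo-F on squared Euclidean distances between arrays, exact over the 35 splits of 8 arrays into 4 and 4. Gene lists with 5 or more measured genes were tested with camera at its preset inter-gene correlation of 0.01, and with camera with an estimated correlation and fry beside it. Of the lists fixed in advance, 24 were tested. Egg envelope glycoproteins had 3 measured genes, sex chromosome genes 2 and meiotic recombination 0, and these were too small to test. List means per array were also compared by exact permutation. The code was tested on simulated data, where camera found a raised list of 20 genes in 10 of 10 runs and an unchanged list in 0 of 10 runs, and limma's unadjusted count averaged 582.5 with no change. The simulated genes varied independently of each other, so these runs do not show how often camera calls an unchanged list of correlated genes.

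The named genes followed a rule set before the data were examined, as were the main tests, the gene lists and the first group of other settings below. The rule took up to 10 genes per direction among those that passed, filled up with the smallest unadjusted p among genes whose groups did not overlap. It added up to 4 passing members of each list, or the 2 of smallest unadjusted p, and a fixed set of gonad genes where the array named them. Other genes are named where the text says that they were chosen after their values were seen, or as members of the ribosomal and oxidative phosphorylation lists. These last, rplp2.L, rpl35a.S, rpl29.L and cox7b.L, and the egg envelope gene zpd.L were also chosen after their values were seen.

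Other settings chosen at the same time were the replicate number as a block, a trended robust prior, quantile normalization, median centring, a filter on low values, array weights, 1 value per gene, sex-reversed replicate 4 moved to the normal group, each replicate left out in turn, looser thresholds, another distance, and other list tests. The array sets, found by average-linkage clustering on 1 minus Pearson's correlation, and the switch-like probe sets were defined after seeing the data, and every result that uses them was added then. The exact permutation of list means was also added then. Genes by chromosome were not analysed here.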

Results

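Gene expression was measured in the ovary of sexually mature hybrid frogs that had a Xenopus laevis mother and a Xenopus muelleri father. The titles named 4 normal ovaries and 4 ovaries of sex-reversed animals, each a biological replicate on 1 Affymetrix array. How sex was reversed is not given in the sources used here. The source name of all 8 arrays said testis, while titles, descriptions, the treatment protocol and the series design said ovary. The source name of sex-reversed replicate 4 also said normal, and this array was grouped by its title. Each array gave a log2 expression value for 11485 probe sets, and array medians lay between 6.0 and 6.04. X. laevis carries most genes as homeologs, marked by the endings .L and .S in gene symbols. The number of arrays limits the precision of every value below.

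The first comparison asked which transcripts differed between sex-reversed and normal ovary. No probe set passed an adjusted p of 0.05 in limma, with 0 higher and 0 lower, and the lowest adjusted p was 0.434. Egg envelope transcripts, made by the oocyte, had similar values in both groups. The egg envelope glycoprotein zp2.L measured 10.97 ± 0.08 (SD, n = 4) in normal and 10.87 ± 0.18 (SD, n = 4) in sex-reversed ovary. Its relative zp4.S differed by 0.00 ± 0.16 (log2, SE), and zpd.L, the remaining egg envelope gene measured, by 0.00 ± 0.14.

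At an unadjusted p of 0.05, 733 of 11485 probe sets differed in limma, 369 higher and 364 lower in sex-reversed ovary, where 574.25 were expected by chance. The 4 values of one group did not overlap those of the other in 466 probe sets, or 4.06%, against 2.86% expected by chance. The median 95% interval reached 0.479 log2 to either side of the estimate. In 8956 probe sets, or 78.0%, the whole interval lay within a 2-fold change in either direction. In simulated data of the same size, limma recovered 43.8% of 200 probe sets changed 2-fold and 87.6% of those changed 4-fold. Without sex-reversed replicate 2, 2 probe sets passed, rpl27.S (log2 change −3.84, adjusted p = 0.00307 in limma) and atp5pd.S (−2.0, adjusted p = 0.0469). Leaving out normal replicate 1, 2 or 3 gave 1 probe set each, namely a probe set with no listed symbol (log2 change 2.43), mcrs1.L (2.23) and tpst2.L (2.31). In each case the array left out was the normal one nearest the sex-reversed values. For the first it was at 7.08 against 6.74 to 6.98, and for mcrs1.L at 8.22 against 7.89 to 8.23. Over all 8 arrays these 2 probe sets gave 1.77 and 1.64 (adjusted p = 0.727 in limma for both).

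Among named genes with values that did not overlap between the groups, 10 on each side had the smallest unadjusted p, and none passed the adjusted threshold. The higher values in sex-reversed ovary included lhx9.L, a LIM homeobox gene of the early gonad, at 5.11 against 4.15 (log2 difference 0.96 ± 0.17, SE). The glucocorticoid receptor gene nr3c1.L differed by 1.19 ± 0.22, and tlr5.L, a receptor for bacterial flagellin, by 2.12 ± 0.43. The tyrosylprotein sulfotransferase gene tpst2.L differed by 1.86 ± 0.40, and ubtf.S, a factor of ribosomal RNA transcription, by 1.32 ± 0.32. The Wnt receptor genes fzd7.L and fzd1.L differed by 0.84 ± 0.19 and 0.59 ± 0.14. The remaining 3, cir1.L, tpd52.L and tpp1.L, differed by 0.66, 0.79 and 0.78. All 10 had adjusted p values between 0.582 and 0.639 in limma.

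On the lower side, slc35e1.L, a solute carrier family member, had the smallest unadjusted p of any named gene, at 3.65 against 4.78 (log2 difference −1.13 ± 0.16, SE; adjusted p = 0.434 in limma). The keratin genes krt8.1.S and krt7.L, expressed in simple epithelia, differed by −1.43 ± 0.26 and −1.08 ± 0.24. The RNA-binding protein genes hnrnpa1.L and stau1.L differed by −0.80 ± 0.14 and −0.85 ± 0.15. The Wnt feedback gene axin2.L differed by −0.76 ± 0.16 and the Src family kinase gene fyn.L by −0.86 ± 0.17. The ribosomal stalk protein gene rplp1.L differed by −0.72 ± 0.15, the cyclophilin gene ppib.L by −0.65 ± 0.13 and the syntaxin gene stx5.L by −0.70 ± 0.15.

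Other probe sets of these 20 genes did not always follow. For 6 of the 20 the array held 11 further probe sets of the same symbol, of which 8 had the same sign and 2 also reached an unadjusted p of 0.05 in limma, both of fzd7.L. A further fzd7.L probe set reached it in the opposite direction. Several of the same-sign values were far smaller than those of the named probe sets. Those of tpp1.L were 0.0007 and 0.20, those of tpd52.L 0.09 and 0.10, and that of ubtf.S 0.28. The further probe sets of fzd7.L gave 0.57, 1.07, −0.18 and −0.59, and that of cir1.L gave −0.15. Of 7 probe sets of homeologs 5 had the same sign, among them axin2.S at −0.33 and ubtf.L at 0.03. The homeologs of opposite sign were nr3c1.S at −0.21 ± 0.31 (SE) and fyn.S at 0.02 ± 0.15. All 4 other probe sets of hnrnpa1.L and hnrnpa1.S were lower, from −0.18 to −0.70.

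**Figure D1:**
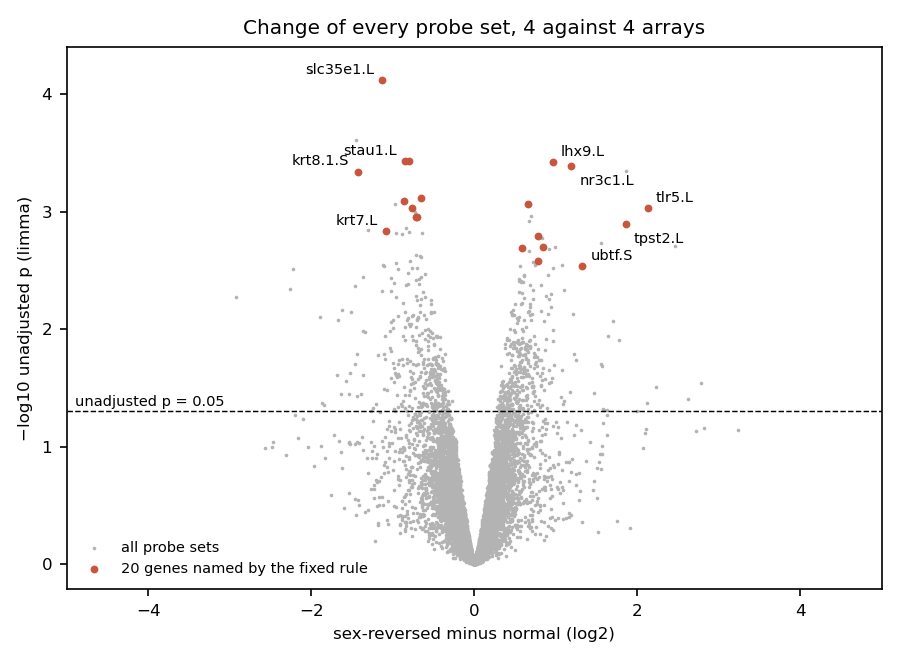
Log2 difference between sex-reversed and normal ovary (x axis) against −log10 of the unadjusted limma p (y axis), 1 point per probe set, with 4 arrays per group. Red points are the 20 genes named by the rule fixed in advance, none of which passed an adjusted p of 0.05, and the dashed line marks an unadjusted p of 0.05.

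Of the genes picked in advance for their role in the gonad, 6 were named on the array. The testis gene sox9.S was at 4.76 against 5.48 in normal ovary (log2 difference −0.71 ± 0.33, SE; adjusted p = 0.787 in limma). The germ cell genes ddx4.L and dazl.L differed by −0.18 ± 0.19 and 0.05 ± 0.27. Normal replicate 3 had ddx4.L at 10.93 and the other normal arrays at 10.15 to 10.32, and without normal replicate 3 ddx4.L differed by −0.01. The probe sets of mos.L, a kinase of oocyte maturation, differed by 0.37 ± 0.19 and 0.02 ± 0.22. The steroid synthesis gene cyp17a1.L differed by 0.01 ± 0.64 and 0.06 ± 1.31 on its 2 probe sets, and the wide errors leave changes above 2-fold open. The sex chromosome list matched 2 measured genes by symbol, capn5.L at −0.19 ± 0.22 and capn5.S at 0.11 ± 0.19. Whether either lies on a sex chromosome was not checked, so they say nothing about sex-linked genes. Genes by chromosome were not analysed here.

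The second comparison asked whether gene groups fixed before the data were examined shifted together, with limma's camera test over 24 lists. Cytosolic ribosomal protein genes were lower in sex-reversed ovary, with 37 of 44 measured genes below the normal mean and a mean log2 change of −0.30 (adjusted p = 8.96e-08 at camera's preset correlation of 0.01). This call was lost with an estimated correlation (adjusted p = 0.273) and in fry, which asks whether the genes move one way on balance (adjusted p = 0.070). Nuclear-encoded genes of oxidative phosphorylation were lower in 35 of 45, with a mean log2 change of −0.17 (adjusted p = 0.00267 at the preset correlation, adjusted p = 0.851 with an estimated correlation). These were the only 2 of 24 lists that passed at the preset correlation, and none passed with an estimated one. Fry's mixed test asks whether genes move in either direction, without a shared one. Its smallest unadjusted p values were those of the testis (1.48e-06), ribosomal (1.66e-05) and mesothelium (7.82e-05) lists.

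The ribosomal list averaged 9.46 ± 0.08 (SD, n = 4) in normal and 9.16 ± 0.11 (SD, n = 4) in sex-reversed ovary, without overlap between arrays. The two-sided exact permutation test gave p = 0.0286, the smallest that 4 against 4 arrays allow, and p = 0.686 after adjustment over 24 lists. A single list at that smallest p could not have passed this adjustment, so the adjusted value does not weigh against the list. Single ribosomal genes included rpl27.S at −2.92 ± 0.79 (log2, SE), rplp2.L at −1.84 ± 0.78, rpl35a.S at −0.46 ± 0.14 and rpl29.L at −0.39 ± 0.14. An unadjusted p of 0.05 was reached by 9 genes on the lower and 0 on the higher side, and rplp1.L alone passed when adjusted over the list alone (adjusted p = 0.0488 in limma), against 0 over all probe sets. The arrays of rpl27.S fell into separate levels, with sex-reversed replicate 2 at 6.83, just below the normal values of 6.85 to 7.11. The other 3 sex-reversed arrays lay between 2.60 and 3.55. Without probe sets of this kind, described further on, the list mean was −0.20 and passed at the preset correlation (adjusted p = 1.55e-06) but not with an estimated one (adjusted p = 0.368).

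The oxidative phosphorylation list averaged 9.05 ± 0.07 (SD, n = 4) in normal and 8.89 ± 0.14 (SD, n = 4) in sex-reversed ovary (two-sided exact permutation p = 0.0857, adjusted p = 0.807 over 24 lists). Genes of ATP synthase gave the lowest values, atp5pd.S at −1.52 ± 0.43 (log2, SE) and atp5mf.S at −0.63 ± 0.22, followed by the cytochrome c oxidase gene cox7b.L at −0.47 ± 0.16. The homeolog atp5pd.L gave −0.16 ± 0.18. No member passed when adjusted over the list alone. The call at the preset correlation was lost without normal replicate 1 (mean −0.13, adjusted p = 0.0785) and without sex-reversed replicate 1 (mean −0.10, adjusted p = 0.252). Sex-reversed replicate 1 had the lowest list value, 8.70, and without it the sex-reversed arrays averaged 8.95 ± 0.08 (SD, n = 3).

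**Figure D2:**
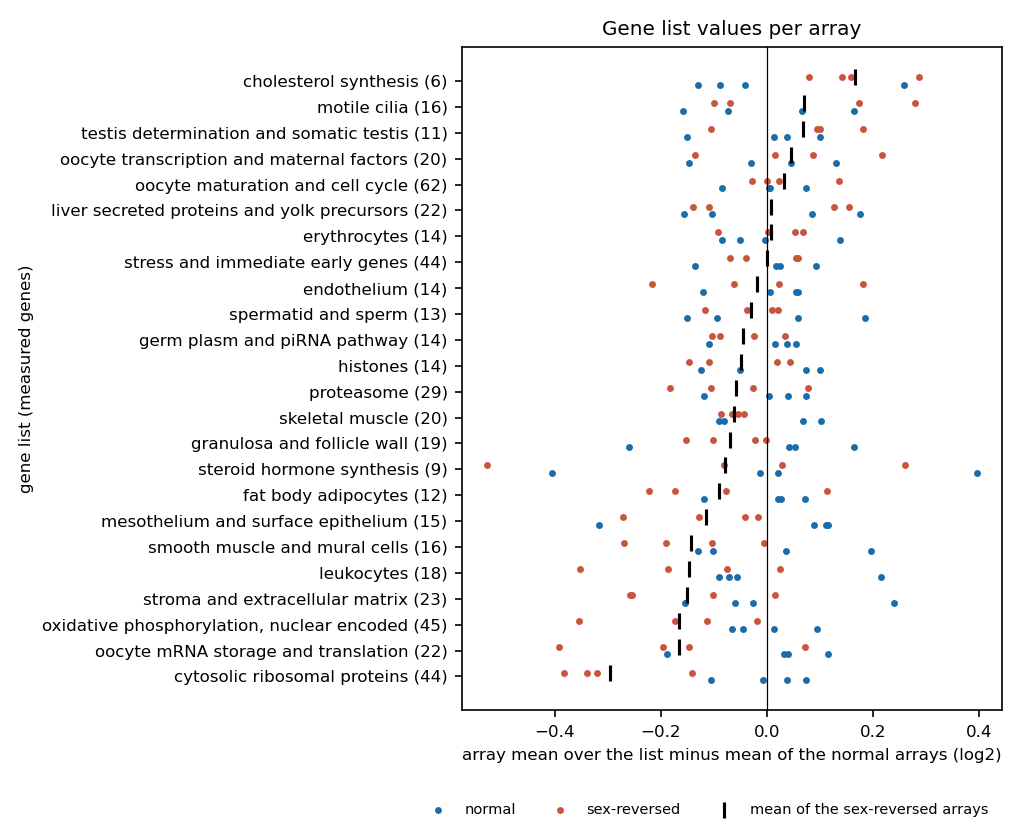
Mean log2 expression of each gene list per array, as the difference from the mean of the 4 normal arrays (x axis), for 24 lists with the number of measured genes in brackets (y axis). Points are single arrays, blue for normal and red for sex-reversed ovary, and black ticks are the means of the 4 sex-reversed arrays. The ribosomal list, at −0.30, is the only one of the 24 in which the arrays of the groups do not overlap.

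None of the oocyte lists passed camera. Of 20 oocyte transcription and maternal factor genes 12 were higher (list mean 0.05), with zar2.S at 0.43 ± 0.21 (log2, SE) and npm3.S at 0.45 ± 0.24. Of 22 genes of oocyte mRNA storage and translation 14 were lower (list mean −0.17), with elavl2-b at −0.41 ± 0.17, and stau1.L was the 1 member that passed when adjusted over the list alone (adjusted p = 0.00822 in limma). Over all probe sets stau1.L did not pass (adjusted p = 0.582 in limma). In the germ plasm and piRNA list 9 of 14 were lower (list mean −0.05), with pld6.S at −0.16 and grip2.L at 0.14. The 62 genes of oocyte maturation and cell cycle held 35 higher members (list mean 0.03), among them the cyclin gene ccnb2.S at 2.12 ± 0.89, whose homeolog ccnb2.L gave 0.02 ± 0.15. Only normal replicates 1 and 4 had ccnb2.S low, at 8.17 and 8.09. Normal replicates 2 and 3, at 11.75 and 11.84, lay among the sex-reversed values of 11.65 to 12.26. The smallest unadjusted p of this list was that of mcm6.2.L, a replication licensing gene, which was lower by 0.44 ± 0.16. It was dim, at 3.08 against 3.52 in normal ovary, below the lower quartile of every array. Probe sets of the homeolog mcm6.2.S gave −0.31 and 0.20. Steroid hormone synthesis had 5 of 9 genes lower (list mean −0.08), with srd5a1.S, a steroid reductase gene, at −0.65 ± 0.27 and fdxr.L at −0.25 ± 0.20.

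The lists of somatic and other cell types did not pass camera either. Of 19 granulosa and follicle wall genes 10 were lower (list mean −0.07), and krt8.1.S passed when adjusted over the list alone (adjusted p = 0.00866 in limma), while the gap junction gene gja1.L was at 0.67 ± 0.47 (log2, SE), with sex-reversed replicates 3 and 4 at 8.81 and 8.91 and the other 2 among the normal values. In the testis list 7 of 11 were higher (list mean 0.07), and lhx9.L passed when adjusted over the list alone (adjusted p = 0.00416 in limma). This list was dim, averaging 4.64 in normal ovary. Mesothelium and surface epithelium had 8 of 15 lower (list mean −0.11), with krt8.1.S and krt7.L both passing when adjusted over the list alone (lowest adjusted p = 0.00684 in limma). Krt8.1.S thus counts in 2 lists. Stroma and extracellular matrix had 12 of 23 lower (list mean −0.15), with the collagen gene col3a1.S at −1.44 ± 0.48 and the growth factor receptor gene pdgfra.L at 0.70 ± 0.27. A further col3a1.S probe set gave −0.08 and a further pdgfra.L probe set −0.12.

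Smooth muscle and mural cells had 11 of 16 lower (list mean −0.14), with tagln.L at −0.98 ± 0.43 (log2, SE) and myh11.S at 0.47 ± 0.26. Skeletal muscle was even at 10 of 20 (list mean −0.06), with acta1.S at −1.47 ± 0.78 and tnnc2.S at 0.33 ± 0.19. Endothelium had 8 of 14 higher, but its list mean was −0.02, with pecam1.L at −0.38 ± 0.14 and cldn5.L at −0.54 ± 0.23, whose homeolog cldn5.S gave 0.35 ± 0.17. Leukocytes were even at 9 of 18 (list mean −0.15, median 0.01), with cd247.S at 0.64 ± 0.21 and lcp1.S at −0.45 ± 0.16. Erythrocyte genes had 8 of 14 lower (list mean 0.01, median −0.03, test direction down), with ca2.L higher at 0.35 ± 0.13 and hbg2.L lower at −0.40 ± 0.18. The homeolog ca2.S gave −0.04 ± 0.13. Liver secreted proteins and yolk precursors had 13 of 22 higher (list mean 0.01), with ambp.L at 1.21 ± 0.35, against −0.17 and −0.20 on its other probe sets, and rbp4.L at 0.56 ± 0.26, against −0.18 for rbp4.S. Fat body adipocyte genes had 7 of 12 lower (list mean −0.09), with dgat2.L, an enzyme of triglyceride synthesis, at −1.25 ± 0.54 and cebpa.L at −0.65 ± 0.24, whose homeolog cebpa.S gave 0.41 ± 0.18. Several of these genes were dim, below the lower quartile of every array (3.99 to 4.05) in both groups. In normal and sex-reversed ovary ca2.L was at 3.03 and 3.37, rbp4.L at 3.06 and 3.63, and tnnc2.S at 3.11 and 3.44. The liver, erythrocyte and skeletal muscle lists averaged 3.95, 4.38 and 4.58 in normal ovary, against array medians of 6.0 to 6.04. Detection was not tested, so the results of such lists say little.

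Motile cilia genes had 9 of 16 higher (list mean 0.07), with cfap36.L at 0.55 ± 0.14 (log2, SE) and rfx2.S, a transcription factor of ciliated cells, at 0.60 ± 0.18. Spermatid and sperm genes had 8 of 13 lower (list mean −0.03), with spag6.L at −0.43 ± 0.25 and crisp1.8.S at 0.28 ± 0.17. All 6 cholesterol synthesis genes were higher (list mean 0.17; camera adjusted p = 0.469), with ebp.L at 0.37 ± 0.18 and cyp51a1.L at 0.25 ± 0.19. In the stress and immediate early list 24 of 44 were higher (list mean 0.00, median 0.04, test direction down), while sgk1.L was at −0.97 ± 0.21 and jun.L at −0.60 ± 0.16. Proteasome genes had 19 of 29 lower (list mean −0.06), with psmd2.L at 0.58 ± 0.23 and psmb4.L at −0.48 ± 0.21. Histone genes were even at 7 of 14 (list mean −0.05), with h2ax.S at 0.57 ± 0.15 and h2bc11.S at −0.44 ± 0.23. Over the 22 lists that did not pass, camera's adjusted p ran from 0.469 to 0.890.

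Most of these small list means depended on single arrays. Leaving out 1 array moved 23 of the 24 list means by more than 1.5 times, all but the ribosomal one, and changed the sign of 8. The mean of oocyte mRNA storage then ran from −0.24 to −0.09, granulosa from −0.16 to −0.01, testis from 0.02 to 0.13 and motile cilia from 0.00 to 0.13. Mesothelium ran from −0.22, without normal replicate 4, to −0.06, stroma from −0.21 to −0.07, smooth muscle from −0.19 to −0.08, leukocytes from −0.21 to −0.08 and fat body from −0.16 to −0.05. Germ plasm ran from −0.08 to −0.03, skeletal muscle from −0.09 to −0.03, proteasome from −0.10 to −0.02, histones from −0.09 to −0.01 and cholesterol synthesis from 0.12 to 0.25. The 20 genes of smallest p were chosen on these same arrays for groups without overlap, which favours stable values. None of these moved by more than 1.5 times, which is therefore no separate evidence for them. Of all 72 probe sets of genes named by the rule, 26 did. The values nearest 0 were −0.85 for acta1.S, −0.62 for tagln.L, 0.45 for pdgfra.L, −0.43 for cebpa.L, −0.43 for srd5a1.S, 0.37 for psmd2.L, 0.36 for gja1.L, −0.36 for cldn5.L, 0.33 for rbp4.L, −0.31 for psmb4.L, 0.23 for npm3.S, −0.22 for spag6.L, 0.18 for tnnc2.S and 0.15 for cyp51a1.L. Those of pld6.S, grip2.L, fdxr.L, zp2.L, capn5.L and capn5.S were −0.10, 0.09, −0.09, −0.02, −0.06 and 0.02.

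The third comparison asked whether whole expression profiles separated by group, and no separation was detected over all arrays. The groups accounted for 14.4% of the variance between arrays (pseudo-F 1.01 on squared distances between arrays, one-sided exact permutation p = 0.457 over 35 splits, smallest possible 0.0286). Pairs of arrays of the same group had a median correlation across probe sets of 0.950, and pairs of different groups 0.953.

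The arrays instead fell into 2 sets of 4 that cut across the groups. One set held normal replicates 1 and 4 with sex-reversed replicates 3 and 4, and the other held normal replicates 2 and 3 with sex-reversed replicates 1 and 2. Correlations ran from 0.954 to 0.972 within a set and from 0.943 to 0.953 between sets. The sets were read from the data by clustering, so their share of variance, 29.2%, is not an independent test. Within sets, pairs of the same group had a median correlation of 0.964 and pairs of different groups 0.959, and between sets 0.949 and 0.946, so the lower value of same-group pairs over all arrays came with fewer of them sharing a set, 4 of 12 against 8 of 16. With the set as a block, limma again passed 0 probe sets (908 at an unadjusted p of 0.05), and the pseudo-F was 1.53 (exact permutation p = 0.0556, the smallest that 18 splits allow). Within the first set limma passed 30 probe sets and within the second 5, at 2 against 2 arrays, and 0 were shared. The ribosomal list was lower within both sets, by a mean of −0.32 (camera adjusted p = 0.00260 at the preset correlation) and −0.27 (adjusted p = 0.000889), but passed in neither with an estimated correlation (adjusted p = 0.923 and 0.896). Because the arrays of the groups did not overlap for this list, a lower mean in both sets had to follow and is no separate evidence. The oxidative phosphorylation list gave −0.17 (adjusted p = 0.134 at the preset correlation) and −0.16 (adjusted p = 0.212).

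**Figure D3:**
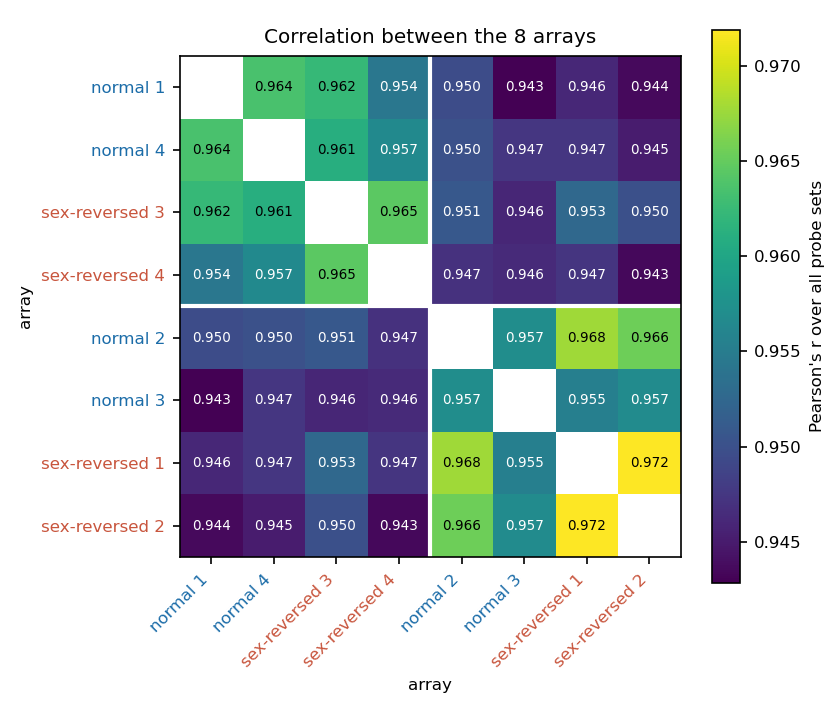
Pearson's r across 11485 probe sets for each pair of the 8 arrays (colour scale), ordered by the sets found by clustering, which white lines separate. Blue names are normal and red names are sex-reversed ovary, and values lie between 0.954 and 0.972 within a set and between 0.943 and 0.953 between sets.

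Several probe sets moved between separate levels rather than over a continuous range. In 282 probe sets, neighbouring ranked values were at least 2 log2 units apart, here called switch-like. Of these, 96 set 1 array apart from 7, 82 set 2 apart from 6, 75 set 3 apart from 5 and 29 divided the arrays 4 against 4. Of the 29, 15 followed the array sets, 0 followed the study groups and no other split had more than 3. The dUTPase gene dut.L was at 3.83 to 4.38 in the first set and 8.79 to 8.92 in the second. The glutathione transferase gene gsta1.L was at 7.87 to 11.2 in the first set and 2.87 to 3.80 in the second. The nitrilase family gene nit2.S and the kinase gene camk4.L were higher in the first set by 4.27 and 3.75. The genes vps4a.L and mettl25b.L were lower there by 3.35 and 3.12. These genes were singled out after their values were seen.

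**Figure D4:**
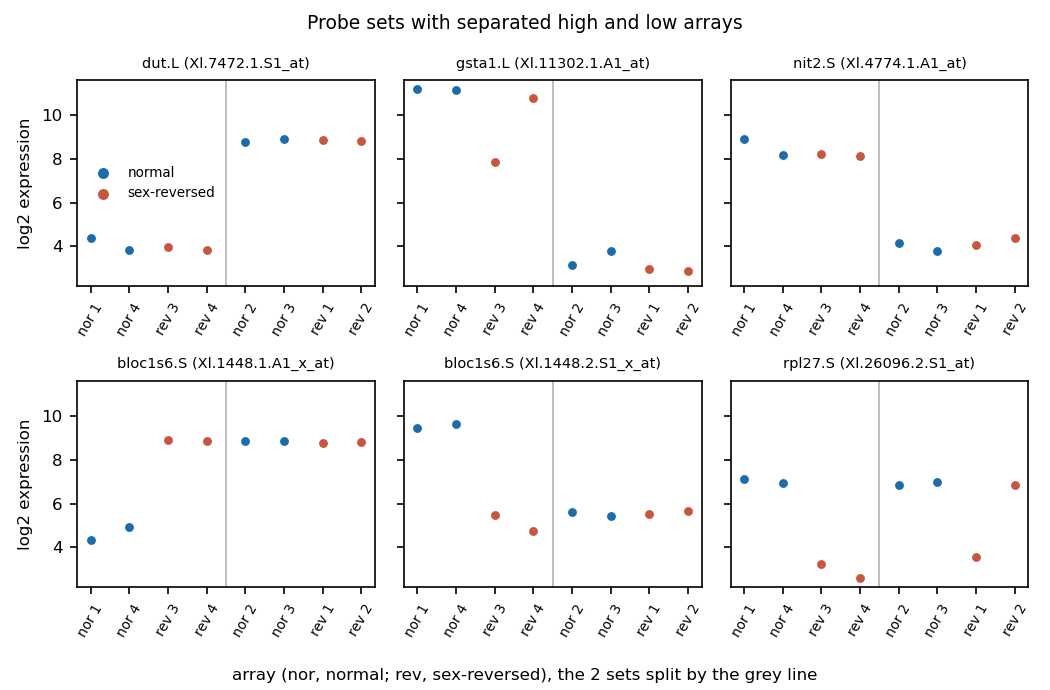
Log2 expression (y axis) of 6 probe sets chosen after their values were seen, 1 point per array, blue for normal and red for sex-reversed ovary, with a grey line between the 2 array sets. The genes dut.L, gsta1.L and nit2.S follow the sets, 2 of the 4 probe sets of bloc1s6.S move in opposite directions in normal replicates 1 and 4, and rpl27.S is low in 3 of 4 sex-reversed arrays.

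The last comparison asked whether one group was more variable than the other. Per array, the median absolute deviation from the group mean was 0.198 ± 0.014 (SD, n = 4) in normal and 0.183 ± 0.012 (SD, n = 4) in sex-reversed ovary. The difference of −0.015 lay within what reassigning the arrays gave (two-sided exact permutation p = 0.20).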

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

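No test in this part was chosen after its result was seen: the rule for arrays that stand apart was fixed before the data were examined. A value was listed when its distance to the nearest other array of its group took up more of the group's range than Dixon's 95% limit for 4 values allows. Of 196 groups of 4 values examined, 9 met it, and chance alone gives about 9.8.

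Normal replicate 3 had tpst2.L at 9.195, while the other 3 normal arrays lay between 7.344 and 7.384, and without it tpst2.L passed in limma (log2 change 2.31, adjusted p = 0.00203). The same array had the leukocyte list at 5.274, above the other normal arrays at 4.968 to 5.003. Sex-reversed replicate 1 stood apart in 3 genes, with ppib.L at 10.35 against 10.22 to 10.24, npm3.S at 8.919 against 8.681 to 8.714, and rfx2.S at 6.495 against 6.915 to 6.993. Sex-reversed replicate 3 had cir1.L at 6.996, below the 7.135 to 7.148 of its group. Sex-reversed replicate 4 had ccnb2.S at 11.65 against 12.21 to 12.26, and a median absolute deviation from its group mean of 0.2014 against 0.176 to 0.1792. Normal replicate 4 had the mesothelium and surface epithelium list at 7.131, below the other normal arrays at 7.537 to 7.564.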

How the results depend on the processing

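The array set block, the fits within each set and the omission of switch-like probe sets, these 2 also with an estimated correlation, were chosen after seeing the data, and all other settings before. The count of passing probe sets stayed at 0 in every fit over all 8 arrays, at 0.05 and 0.10, and leaving out a replicate gave 0 to 2. It was 30 within array set 1 and 5 within array set 2, and 733 at an unadjusted p of 0.05. That last count was 380 with the filter on low values, which tests 5742 probe sets, and 587 to 796 with a replicate left out. Whether replicate numbers paired the samples was not settled. Deviations of same-numbered arrays correlated at −0.19, 0.24, −0.19 and 0.17, and not every array correlated best with its own number. The sign followed the array sets in every pair of a normal with a sex-reversed array, so a pairing beneath the sets cannot be told apart. With the replicate number as a block, 0 probe sets passed and 663 reached an unadjusted p of 0.05. The pseudo-F lay between 0.940 and 1.12 with a replicate left out. The difference in spread was −0.021 with the filter on low values (exact permutation p = 0.0571). The number of lists past camera's threshold, 2, became 0 with an estimated correlation and 0 in fry. It was 1 within array set 1 and 1 within array set 2, each 0 with an estimated correlation, 0 with an estimated correlation and without switch-like probe sets, and 1 to 3 with a replicate left out. The list gained without normal replicate 3 was cholesterol synthesis (0.25, adjusted p = 0.0464), and the filter on low values brought stroma and extracellular matrix past the threshold (−0.39, adjusted p = 0.0370). Within array set 1, tpst2.L, ccnb2.S and rpl27.S passed. The remaining causes were not tested. The test of genes by chromosome was not run, because no chromosomes were used here. Lists left with fewer than 5 genes by the filter gave no value. Signal over background was not used here, so limits for dim probe sets are unknown.

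Changes of sign were seen in values near 0 that passed neither limma nor a list test of shared direction, and the cause was not tested. Array weights gave zp4.S at −0.0013. With sex-reversed replicate 4 moved to normal, capn5.S was −0.064, cyp17a1.L −0.042 and −0.17, the testis list −0.0067, spermatid and sperm 0.021, liver secreted proteins −0.071 and histones 0.014. Within array set 1, zp4.S was −0.088, fdxr.L 0.080, capn5.S −0.081, mos.L −0.17 and cyp17a1.L −0.38. The lists there were −0.048 for oocyte transcription, 0.0084 for germ plasm, 0.058 for steroid synthesis, 0.045 for spermatid and sperm, 0.021 for skeletal muscle, 0.072 for endothelium, −0.039 for erythrocytes and −0.013 for stress genes. Within array set 2, dazl.L was −0.035, cyp17a1.L −0.0018, motile cilia −0.088, liver secreted proteins −0.087 and histones 0.042. Without switch-like probe sets, oocyte maturation was −0.017 and endothelium 0.046. The filter on low values gave granulosa 0.012, mesothelium 0.12 and stress genes −0.048. The mean of probe sets per gene gave liver secreted proteins −0.035 and stress genes −0.017. With a replicate left out, zp4.S ran from −0.10 to 0.078, dazl.L from −0.12 to 0.30, mos.L from −0.11 to 0.14, and cyp17a1.L from −0.48 to 0.51 and from −0.93 to 1.22. The lists ran from −0.011 to 0.11 for oocyte transcription, −0.0020 to 0.057 for oocyte maturation, −0.21 to 0.070 for steroid synthesis and −0.081 to 0.032 for spermatid and sperm. They ran from −0.085 to 0.048 for endothelium, −0.020 to 0.054 for erythrocytes, −0.044 to 0.067 for liver secreted proteins and −0.044 to 0.032 for stress genes.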

Other observations

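Tests chosen only after the result was seen are those within the array sets, except the one on changes shared by both, and those with the sets as a block, over splits of the arrays, on other probe sets of the same genes, on overall signal, on somatic markers, without switch-like probe sets and on the position of sex-reversed replicate 4. The array sets and switch-like probe sets were themselves read from the data. The test of other probe sets of the same genes was first restricted to gaps of 2 log2 units or more, had no pairs for the array sets, and was then widened to gaps of 1.

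Within the first array set, 2 sex-reversed against 2 normal arrays, the largest changes of named genes among the 30 that passed limma were probe sets of ddt.L, a tautomerase gene, at 6.29 (log2), the splicing factor gene srsf2.L at −5.55 and the V-type ATPase gene atp6v1c1.L at −4.99. The same probe sets gave 0.17, 0.42 and 1.07 in the second set. The mitotic checkpoint gene bub1b.L gave 3.42 and −0.36, and rplp2.L gave −3.64 and −0.05. All 5 are switch-like, as are 23 of the 30 and 4 of the 5 that passed in the second set, so they may reflect single probe sets rather than transcript levels. Between the low and high arrays the other probe set of srsf2.L differed by −0.20, and those of atp6v1c1.L by −0.07 and −0.20. In the second set probe sets of the kinase gene dapk2.L gave 4.05 and kansl2.S −5.0, against 0.42 and 0.07 in the first. Of the 30 changes of the first set 12 had the same sign in the second, as had 3 of 5 in the other direction, and 0 passed in both. Other ways of dividing the same 4 arrays 2 against 2 passed at most 1 probe set in either set. Each set allows only 3 such splits, the real one included, and the sets were read from these same values, so this comparison cannot decide.

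A hypothesis is that a group difference common to both sets may lie beneath the set structure. It was tested by correlating the log2 changes of the sets across all probe sets, which are not independent of each other. Pearson's r was 0.063 and Spearman's rho 0.112, and 3 of 18 arrangements of the arrays within the sets gave a Pearson's r as high, with 0.0665 the highest of the others. The test leaves the hypothesis open.

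The number of probe sets that passed limma was 0 for the study groups, and 35 of the 35 splits of the 8 arrays gave as many, with 103 the highest of the others. With a count of 0 this holds for any split and tells nothing about chance. At an unadjusted p of 0.05 the real count was 733, and 5 of 35 splits gave as many, but the other 4 divided the array sets unevenly. The highest other count, 1429, and the 103 came from the split along the array sets, which were found by clustering these same values. Of the 18 splits that keep 2 arrays of each set on either side, only 1, the real one, gave as many as 733, and the highest other count was 658. With the set as a block, 0 probe sets passed and 908 reached an unadjusted p of 0.05, against at most 788 in the other balanced splits. The smallest share that 18 splits allow is 0.0556, so chance can be neither excluded nor supported.

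The division of the arrays into sets was set against sequence variants, other cell types and overall signal. No cell type list reached the 2 times the median absolute difference of all genes that mixing was held to need. The highest were fat body adipocytes at 1.59 and endothelium at 1.48. This argues only against a large shift of these markers. The measure ignores direction, and lists such as endothelium (mean 4.81 in normal ovary) were dim, so smaller shifts in other cell types stay open. Probe sets that separated the sets by 1 log2 unit or more were not followed by other probe sets of the same genes, with a median ratio of −0.016 over 6 pairs, nor were switch-like probe sets as a whole (0.025 over 95 pairs), which is consistent with alleles that bind single probe sets differently. Overall signal cannot be told apart, because 0 of median and interquartile range separated the sets but RMA fixes both. No relation between the animals or hybridisation batch was given in the labels, so shared parents and a batch stay open as untested explanations of the sets.

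Over all switch-like probe sets, 95 pairs with another probe set of the same gene, from 46 genes, had a median ratio of 0.025, with 73 pairs under 0.25 and 10 at 0.75 or more. Of the 4 probe sets of bloc1s6.S, 3 were lower in normal replicates 1 and 4, by 4.22, 2.97 and 1.15, and 1 was higher there, by 4.16. Probe sequences and genotypes were not used here, and splice forms and cross-hybridisation were not tested.

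The lower ribosomal protein values were set against brightness, sequence variants and fewer somatic cells. Of 10000 random lists matched on brightness 0 had a mean as low as the ribosomal list, and 3 had one as low as the oxidative phosphorylation list, which argues against brightness of the probe sets. Switch-like variants were not the whole cause, since the ribosomal mean without them was −0.197 against −0.296, although variants with smaller effects stay open. A lower share of somatic cells cannot be told apart: 22 somatic markers had a median change of −0.109 (bootstrap interval −0.235 to −0.0797), which reaches the ribosomal median of −0.225. This interval came from resampling genes, treated as independent, and leaves out the spread between arrays. It therefore does not show that somatic markers were lower. Sex reversal, the difference the design names, also stays open, and so does chance among correlated genes, given the adjusted p of 0.273 with an estimated correlation.

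Sex-reversed replicate 4, whose source name said normal, lay nearer the mean of the normal arrays (61.4) than that of the other sex-reversed arrays (64.6). That position decides nothing about a mislabelled sample, because only 2 of the other 7 arrays lay nearer their own group, and the normal mean held 2 arrays of its set against 1 in the other. Within its set it correlated best with sex-reversed replicate 3 (0.965, against 0.957 and 0.954 with the normal arrays), as 6 of the other 7 arrays did with the array of their own group, but 1 such array for each is too few to decide. Moved to the normal group, it left 0 probe sets passing in limma and a ribosomal list mean of −0.22. These profiles leave a wrong label open.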
